A study of Homo sapiens with 4 samples.

How the data were processed

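The series holds 4 RNA-seq libraries of an established human renal cell carcinoma line, the one the labels name. Per the labels, 2 libraries came from cells transfected with control siRNA (Control 1 and Control 2) and 2 from cells transfected with siRNA against SLFN5 (called SLFN5 siRNA 1 and SLFN5 siRNA 2 here). Per the labels' protocols, total RNA was selected for poly(A) with the Illumina TruSeq RNA v2 kit and read as single ends on a HiSeq 2500. Some RNAs without a poly(A) tail nevertheless took large shares of the counts, such as RN7SK with 2.20% to 3.76% per library. The submitters' processing notes name hg19 as the genome build and edgeR as a tool the submitters used. The aligner, the counting program and the annotation version are not given in the sources used here. The series' design text speaks of triplicates, whereas 4 libraries were analysed here. No label says that the libraries of a group came from separate cultures. The p-value of a single gene below thus rests on a spread between libraries, moderated over genes, that may be technical. A list p-value from camera with the preset correlation (described below) sets list members against other tested genes. It does not measure how a list varies between cultures.

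The deposited table lists 57659 Ensembl genes, of which 2682 carry no gene name. The deposited values are a signal per gene that the authors made from read counts: they are not whole, and genes without reads stand at a value near 0. The low values lie where the quantile adjustment of counts to one common library size (the pseudo-counts that the authors' tool, edgeR, makes) would put them, within each group of 2 libraries. They are called equalised counts here. The planned test assumed raw counts. Because the deposited values are not counts, the replacement fixed beforehand was used: limma on log2(value + 1).

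The adjustment was inverted to find the sequencing depth. With a common dispersion of 0.0162, all 230636 values corresponded to whole counts (tolerance 1e-06), and putting those counts through the same adjustment returned the deposited values to within a relative difference of 1.11e-09. On simulated counts the inversion returned 100% of 230636 values. The recovered totals were 31905328 counts in Control 1, 13187517 in Control 2, 17117659 in SLFN5 siRNA 1 and 14700669 in SLFN5 siRNA 2. The recovered counts served for depth, for scaling alternatives, for thinning and for limma-voom, and a count model was not run on them. Within groups the recovered counts differed far beyond sampling noise (chi-square per degree of freedom 18.0 for the controls and 17.8 for SLFN5 siRNA), which does not tell separate cultures from separate preparations of the same culture. All 4 libraries were analysed, 2 per group.

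Genes with an equalised count of at least 10 in at least 2 libraries were tested (15640). This filter, the pseudocount of 1 and the trend in the variance were set once the unit of the values was known. Values were transformed as log2(value + 1), and limma 3.58.1 in R 4.3.3 fitted the group alone, with an intensity trend in the moderated variance and Benjamini-Hochberg adjustment over all genes tested. An adjusted p of a gene given below without an alternative or a left-out library comes from this limma fit (prior degrees of freedom 9.60, residual 2), with a threshold of 0.05. A fold change on this scale understates the change of genes with low values. The script was tested on simulated counts with 200 changed genes among the real means and depths. Of the 15465 genes tested there, it called 88.2% of genes set to 2 times and 69.7% of genes set to 0.5 times, but 26.5% of those set to 1.5 times and 21.2% of those set to 0.67 times. It called 3 unchanged genes. In the simulation, changes of those last sizes were thus missed more often than not. It used 200 changed genes and the common dispersion for every gene, whereas 4630 genes passed in the data. These shares therefore need not hold for the data. A gene past no threshold is still not shown to be unchanged.

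Gene lists, the planned tests with their replacement, the alternatives (apart from those said below to be chosen later) and the rule for named genes were fixed before the data were examined. The 23 lists include Schlafen genes, matrix metalloproteinases and their inhibitors, other secreted proteases, extracellular matrix, integrins and focal adhesion, epithelial-mesenchymal transition (EMT) genes, TGF-beta targets, interferon-stimulated genes, NF-kB and cytokine genes, HIF and hypoxia targets, cell cycle genes, p53 targets, the unfolded protein response, cholesterol biosynthesis, proximal tubule, leukocyte, fibroblast and endothelial markers, the mitochondrial genome, replication histones, ribosomal proteins and the small RNA pathway. No gene stood in more than a single list. The 19 lists with at least 5 tested members were compared with all other tested genes by camera (limma, two-sided, preset inter-gene correlation 0.01, Benjamini-Hochberg over the lists), leaving SLFN5 out. Counts of members past the threshold are given over all genes tested and adjusted over the list alone. The named genes are SLFN5; a panel that includes MMP1, MMP13, MMP2, MMP9, MMP14, SLFN11, SLFN12, SLFN13 and IRF1; the 10 higher and 10 lower genes with the largest absolute log2 change among genes past the threshold whose groups do not overlap and whose mean log2 CPM is at least 1; and up to 4 members of each list past the threshold with the largest absolute change. Genes named outside that rule are said to be so, and not every gene or list that the rule covers is given.

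The alternatives were RLE and upper-quartile scaling, library totals without composition scaling, no filter and a filter on CPM above 1, limma-voom on the recovered counts, the replicate number as a block, leaving out each library in turn, thinning to the shallowest library, pseudocounts of 0.25 and 4, an adjusted p under 0.01, a minimum absolute log2 change of 1, camera with an estimated correlation and fry. A trend on transcript length and GC content was also removed, and genes with certain 3' UTR hexamers were left out. These 2 were chosen after seeing the data. Transcript lengths, GC contents, gene types and 3' UTR sequences came from GENCODE (GRCh38), matched by Ensembl gene ID. That build differs from the files' build, so no coordinates are given. The length and GC content of a gene were those of its longest annotated transcript, found for 96.7% of the tested genes.

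For the 3' UTR analysis the longest annotated 3' UTR of each of 10546 tested genes (50 to 10000 bases, mean log2 CPM of at least 1) was searched for each of 15670 7-base words present in at least 100 genes. The log2 change was regressed on the presence of the word, on log2 UTR length and GC content, on their squares and on their product. On log2 changes shuffled over genes after the trend on length and GC content was taken out, with a shift of -0.2 planted on a random word, the planted word ranked lowest in 10 of 10 draws. For words of the same bases, the searched genes were divided at random into 2 sets of 5273, and the lowest and highest word of each set (present in at least 50 genes of it) was compared in the other. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 was used, and matplotlib 3.10.9 for plots.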

Results

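Human Schlafen 5 (SLFN5) belongs to a family of interferon-regulated growth regulators, and the series title ties it to the motility and invasiveness of renal carcinoma cells. Gene expression was measured by RNA-seq in a human renal cell carcinoma line, in 2 libraries after control siRNA and 2 after siRNA against SLFN5. The question was which transcripts differ when SLFN5 is reduced. The recovered depth was 31905328 counts in Control 1, 13187517 in Control 2, 17117659 in SLFN5 siRNA 1 and 14700669 in SLFN5 siRNA 2, so Control 1 was 2.42 times as deep as Control 2. Values are equalised counts given as mean ± SD (n = 2 libraries per group), and log2 changes are SLFN5 siRNA minus control with the standard error (SE).

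The target was reduced in both libraries. SLFN5 (ENSG00000166750) stood at 420 and 353 equalised counts in the control libraries and at 167 and 118 in the SLFN5 siRNA libraries. The means were 387 ± 47.7 and 142 ± 34.4 (SD, n = 2), a log2 change of -1.45 (SE 0.21), or 0.366 of the control level (limma, adjusted p = 0.000524). Of the other Schlafen genes, SLFN11, which sensitises cells to DNA damage, fell by 0.93 on the log2 scale (SE 0.13, adjusted p = 0.000305), from 1352 ± 67.4 to 708 ± 23.7 (SD, n = 2). SLFN12 fell by 0.64 (SE 0.19, adjusted p = 0.0249), a call lost without Control 2 (adjusted p = 0.0925), without SLFN5 siRNA 1 (log2 change -0.41, adjusted p = 0.136) and with library totals alone (0.0568). SLFN13, near the detection limit at 20.3 and 22.4 mean equalised counts, did not pass (log2 change 0.05, SE 0.56, adjusted p = 0.961). Thus 2 of the 3 tested Schlafen genes other than SLFN5 were lower, also 2 when adjusted over the list alone. SLFN12L and SLFNL1 had 26 and 22 recovered counts over all 4 libraries and SLFN14 had 0, too few to test.

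**Figure D1:**
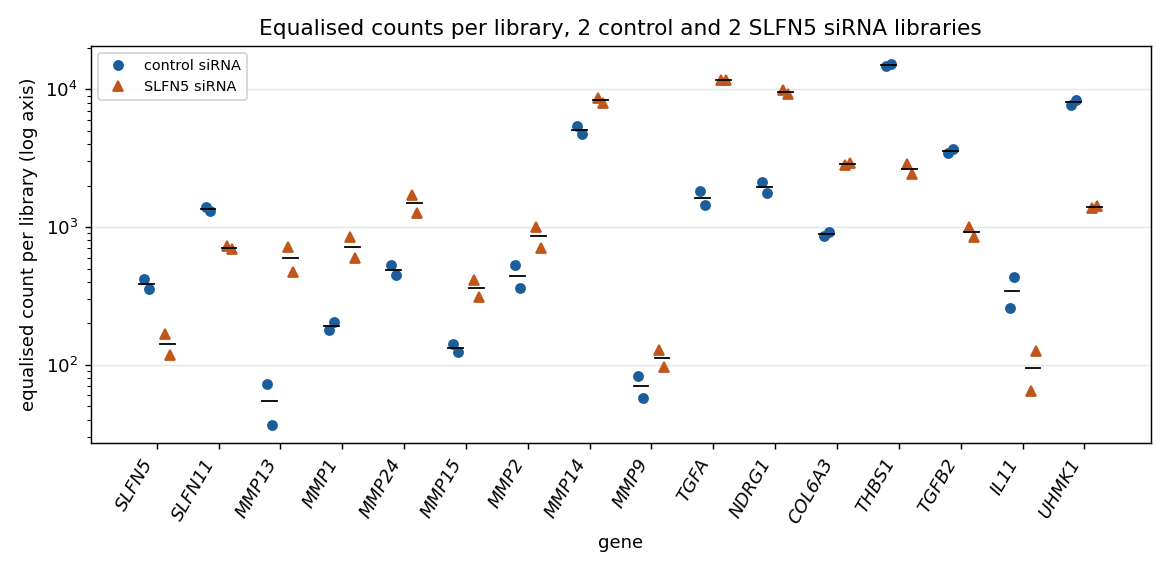
Equalised counts of 16 named genes in each library, on a log axis, with circles for the 2 control libraries, triangles for the 2 SLFN5 siRNA libraries and black bars for the group means. SLFN5 lies at 420 and 353 in the controls against 167 and 118 after SLFN5 siRNA, while MMP13 lies at 72.8 and 36.8 against 716 and 470.

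Several matrix metalloproteinase genes were higher after SLFN5 siRNA. MMP13 (ENSG00000137745), a collagenase, had the largest increase of the genes named by size, from 54.8 ± 25.5 to 593 ± 173 equalised counts (SD, n = 2; log2 change 3.46, SE 0.31, limma adjusted p = 2.74e-05). MMP1 (ENSG00000196611), the interstitial collagenase, rose 3.71-fold from 191 ± 17.2 to 721 ± 177 (log2 change 1.89, SE 0.19, limma adjusted p = 5.50e-05). The membrane-type enzymes MMP24 and MMP15 rose 3.04-fold and 2.69-fold, and MMP14, which activates pro-MMP2, by 0.72 on the log2 scale (SE 0.11, adjusted p = 0.000762). The gelatinase MMP2 rose by 0.95 (SE 0.21, adjusted p = 0.00525). MMP9, also a gelatinase, had a log2 change of 0.67 (SE 0.29) that did not pass (adjusted p = 0.105). Of the 14 tested metalloproteinase and inhibitor genes, 8 were higher, 0 were lower and 6 did not pass, with 8 and 0 when adjusted over the list alone. The other 2 were MMP16 and TIMP2, an inhibitor of these enzymes (log2 changes 0.72 and 0.68; both outside the rule for named genes and chosen after their values were seen). The list stood above the other genes in camera (median log2 change 0.72, adjusted p = 0.00105). With an estimated correlation the call was lost (camera adjusted p = 0.826). Here and for the lists below, that run rests on 2 residual degrees of freedom and has little power. It was also lost when genes with certain 3' UTR hexamers were left out (camera adjusted p = 0.161), which takes out at least 8 of the 14 members.

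Other secreted proteases and their inhibitors went both ways, with 5 of 21 higher and 9 lower, and the same counts adjusted over the list alone. The matrix protease ADAMTS6 fell by 1.52 on the log2 scale. The tissue plasminogen activator PLAT, at 42.8 mean equalised counts in the controls, had a log2 change of -1.58 (adjusted p = 0.0187), and ADAMTS15 one of -1.35 (adjusted p = 0.0110). PLAT did not pass without Control 1 (0.0571), Control 2 (0.134) or SLFN5 siRNA 2 (0.0609) or at the depth of the shallowest library (0.0640), nor ADAMTS15 without Control 1 (0.121) or SLFN5 siRNA 2 (0.0532). The list did not stand apart from other genes (camera adjusted p = 0.261).

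Matrix and adhesion genes changed in both directions. Of 36 tested extracellular matrix genes 9 were higher and 9 lower (11 and 10 adjusted over the list alone; camera adjusted p = 0.668). The matricellular protein thrombospondin-1 (THBS1) fell from 14982 ± 434 to 2650 ± 300 equalised counts (SD, n = 2; log2 change -2.50, SE 0.11, limma adjusted p = 4.21e-07), and tenascin C (TNC) fell by 1.71 on the log2 scale. The collagen VI chains COL6A3 and COL6A1 rose by log2 changes of 1.68 and 1.38. Among 32 integrin and focal adhesion genes, 7 were higher and 5 lower (8 and 5 adjusted over the list alone; camera adjusted p = 0.261). The integrin activator FERMT2 fell by 1.24 on the log2 scale, and the docking proteins NEDD9 and TNS1 rose by 1.23 and 1.10. FERMT1, at 51.0 mean equalised counts in the controls, had a log2 change of -1.93 (adjusted p = 0.00931) and did not pass without Control 1 (adjusted p = 0.120).

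Transition genes also split. Of 22 EMT genes, 4 were higher and 6 lower (5 and 6 adjusted over the list alone; camera adjusted p = 0.668), with a median of -0.12 and a mean of 0.05. The junction protein plakoglobin (JUP), the epithelial adhesion molecule EPCAM and the kidney cadherin CDH6 rose by log2 changes of 2.52, 1.57 and 1.42 (CDH6 0.87 without Control 2), and WNT5B fell by 1.51. Of 22 TGF-beta targets, 5 were higher and 6 lower (6 and 6 adjusted over the list alone; camera adjusted p = 0.668). The ligand TGFB2 fell from 3576 ± 198 to 922 ± 109 equalised counts (SD, n = 2; log2 change -1.96, SE 0.12, limma adjusted p = 4.36e-06) and LTBP2 fell by 0.99, while the cycle inhibitor CDKN1A rose by 0.99 (0.64 without Control 2). LTBP1, at 14.9 mean equalised counts in the controls, had a log2 change of 1.32 (adjusted p = 0.0362) that did not pass in any fit leaving out a library, with adjusted p from 0.0668 to 0.173. The TGF-beta list had a positive median (0.14) and mean (0.02) but a negative direction in fry.

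Among inflammatory genes more were lower than higher. Of 34 NF-kB and cytokine genes, 13 were lower and 2 higher (13 and 3 adjusted over the list alone). The cytokine IL11 fell from 346 ± 120 to 95.7 ± 44.0 equalised counts (SD, n = 2; log2 change -1.88, SE 0.32, limma adjusted p = 0.00123), and the apoptosis inhibitor BIRC3 fell by 1.43 on the log2 scale. The mitochondrial superoxide dismutase SOD2 rose by 1.41. The chemokine CCL20, at 25.2 mean equalised counts in the controls, had a log2 change of -2.52 (adjusted p = 0.00972) and did not pass without Control 1 (0.0788) or Control 2 (0.0595). The list passed in camera (median -0.39, adjusted p = 0.0233), but not with an estimated correlation (adjusted p = 0.760), nor without Control 2 (adjusted p = 0.0711) or SLFN5 siRNA 2 (0.0622). Its adjusted p ranged from 0.00578 to 0.342 over 16 alternatives.

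Interferon-stimulated genes went both ways, with 7 of 48 higher and 8 lower (7 and 10 adjusted over the list alone; camera adjusted p = 0.668). The interferon regulatory factor IRF1 fell by 0.65 on the log2 scale (SE 0.12, adjusted p = 0.00219), whereas IRF7 rose by 1.51 and IFI35 by 0.91. IFIT2 fell by 1.28, and GBP2 had a log2 change of -1.46 (adjusted p = 0.0162) that did not pass without SLFN5 siRNA 2 (log2 change -0.84, adjusted p = 0.0717).

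HIF and hypoxia targets, of interest because clear cell renal carcinomas often lose VHL, included some of the largest increases. TGFA (ENSG00000163235), a ligand of the epidermal growth factor receptor, rose 7.23-fold from 1628 ± 264 to 11700 ± 91.3 equalised counts (SD, n = 2; log2 change 2.85, SE 0.12, limma adjusted p = 3.95e-07). NDRG1 rose 4.95-fold, the lipase inhibitor ANGPTL4 4.61-fold and the mTOR regulator DDIT4 3.07-fold. Of 40 tested members, 16 were higher and 10 lower, with the same counts adjusted over the list alone. The list did not pass (median 0.07, mean 0.30, camera adjusted p = 0.313). The lower members included the glycolytic enzymes ENO1, PGK1 and LDHA, with log2 changes of -0.51, -0.51 and -0.41. The higher members included the glycolytic enzyme ENO2 and the glucose transporters SLC2A1 and SLC2A3, with log2 changes of 0.60, 0.54 and 0.82. All of these were chosen after their values were seen, and no list of glycolysis genes was tested.

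Among cholesterol biosynthesis genes more were lower than higher. Of 23 tested, 14 were lower and 1, the mevalonate pathway kinase PMVK (log2 change 1.12), was higher, with 15 and 1 adjusted over the list alone. STARD4, a sterol carrier, fell by 1.25 on the log2 scale (SE 0.12), IDI1, the isopentenyl diphosphate isomerase, by 1.19 (SE 0.13), and HSD17B7 by 1.15 (SE 0.17). The list passed in camera (median -0.49, adjusted p = 0.00260), but not with an estimated correlation (adjusted p = 0.879) or without SLFN5 siRNA 2 (adjusted p = 0.0622). Its adjusted p ranged from 7.95e-05 to 0.147 over 16 alternatives.

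Cell cycle genes were mostly lower where they changed, with 15 of 50 lower and 2 higher (17 and 2 adjusted over the list alone). Cyclin E1 (CCNE1) fell by 0.94 on the log2 scale, UHRF1 by 0.75 and the replication factor MCM10 by 0.68. The kinetochore protein CENPF went the other way, from 3160 ± 16.3 to 9544 ± 947 equalised counts (SD, n = 2; log2 change 1.59, SE 0.11, limma adjusted p = 6.57e-06). The list passed in camera (median -0.24, adjusted p = 0.0233), but not with an estimated correlation (adjusted p = 0.760), nor without Control 2 (adjusted p = 0.0711) or SLFN5 siRNA 1 (0.160). Its adjusted p ranged from 0.0105 to 0.160 over 16 alternatives.

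Replication histones, whose transcripts end without a poly(A) tail, were lower in 10 of 26 cases and higher in 0 (15 and 0 adjusted over the list alone; median -0.30, camera adjusted p = 0.00105). With an estimated correlation the adjusted p was 0.760. HIST1H1D, HIST1H2AB and HIST1H3A had log2 changes of -0.71, -0.68 and -0.54, and HIST2H3D had one of -0.62 (adjusted p = 0.0113) that did not pass without Control 2 (0.156). Another transcript without a poly(A) tail, RN7SK, had a log2 change of 0.51 in the other direction (adjusted p = 0.0380; chosen after its value was seen). Histone genes have near-identical copies, so single members are uncertain. Ribosomal protein genes were lower in 17 of 48 cases and higher in 1, RPL11 (log2 change 0.32, chosen after its value was seen), with the same counts adjusted over the list alone (median -0.22, camera adjusted p = 0.00260). With an estimated correlation the adjusted p was 0.760. RPS2, RPL7, RPL5 and RPL37A had log2 changes of -1.21, -0.75, -0.68 and -0.61, and ribosomal protein genes have processed pseudogenes that share sequence. Of 14 mitochondrially encoded genes, 0 were higher and 0 lower in limma, also 0 and 0 adjusted over the list alone, and 2 had an unadjusted p under 0.05 (camera adjusted p = 0.668). Mitochondrial genes held only 0.0440% to 0.0588% of the recovered counts per library.

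Stress and growth-arrest lists did not pass as groups. Of 28 unfolded protein response genes 4 were higher and 9 lower, with the same counts adjusted over the list alone (camera adjusted p = 0.261). PSAT1, an enzyme of serine synthesis, fell by 2.13 on the log2 scale, the cystine transporter SLC7A11 by 1.61 and the chaperone DNAJB9 by 1.22, while the pseudokinase TRIB3 rose by 1.71. Of 25 p53 targets 5 were higher and 4 lower (6 and 6 adjusted over the list alone; camera adjusted p = 0.826), with a median of -0.11 and a mean of 0.06. GADD45A fell by 1.71, while the DNA repair genes XPC and DDB2 rose by 1.43 and 1.00 (DDB2 0.58 without Control 2). SPATA18, at 21.6 mean equalised counts in the controls, had a fold of 3.02 (adjusted p = 0.0199) that did not pass without Control 2 (log2 change 1.01, adjusted p = 0.143) or SLFN5 siRNA 1 (0.119). Of 13 small RNA pathway genes, 1 was higher and 5 lower, with the same counts adjusted over the list alone (camera adjusted p = 0.261). TNRC6A and PRKRA fell by 0.96 and 0.68, and the microRNA processing enzyme DROSHA rose by 0.71. AGO3 had a log2 change of -0.54 (adjusted p = 0.0246) that did not pass without Control 2 (0.162), without SLFN5 siRNA 1 (0.115) or with library totals alone (0.0735).

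Marker lists of kidney tubule and of other cell types had few tested members. Of 9 tested proximal tubule markers 2 were higher and 0 lower (2 and 0 adjusted over the list alone; camera adjusted p = 0.245, and 0.0289 without Control 1). They were CUBN (log2 change 1.88), which did not pass without Control 2 (adjusted p = 0.102) or SLFN5 siRNA 2 (0.0769), and ANPEP (0.69), which did not pass without Control 2 (log2 change 0.38, adjusted p = 0.350), SLFN5 siRNA 1 (0.115) or SLFN5 siRNA 2 (0.0600) or at the depth of the shallowest library (0.0568). Of 13 leukocyte markers 3 were tested, and CD68, a lysosomal protein also made by other cells, rose from 196 ± 11.5 to 577 ± 31.2 equalised counts (SD, n = 2; log2 change 1.56, limma adjusted p = 7.03e-05). It was the only called member over all genes, against 2 adjusted over the list alone, while PTPRC had 1 recovered count over 4 libraries and CD3E had 0. Of 4 tested fibroblast markers, 2 were higher and 1 lower (2 and 1 adjusted over the list alone). ACTA2 (log2 change 1.33) did not pass without Control 2 (log2 change 0.83, adjusted p = 0.176) or SLFN5 siRNA 2 (0.157), COL14A1 (1.09) without Control 2 (log2 change 0.60, adjusted p = 0.185) or SLFN5 siRNA 1 (0.0743), and PDGFRB (-1.82) without Control 1 (0.148), Control 2 (0.135) or SLFN5 siRNA 1 (0.114). The 1 tested endothelial marker, ESAM, did not pass over all genes (log2 change 1.71, adjusted p = 0.0595).

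**Figure D2:**
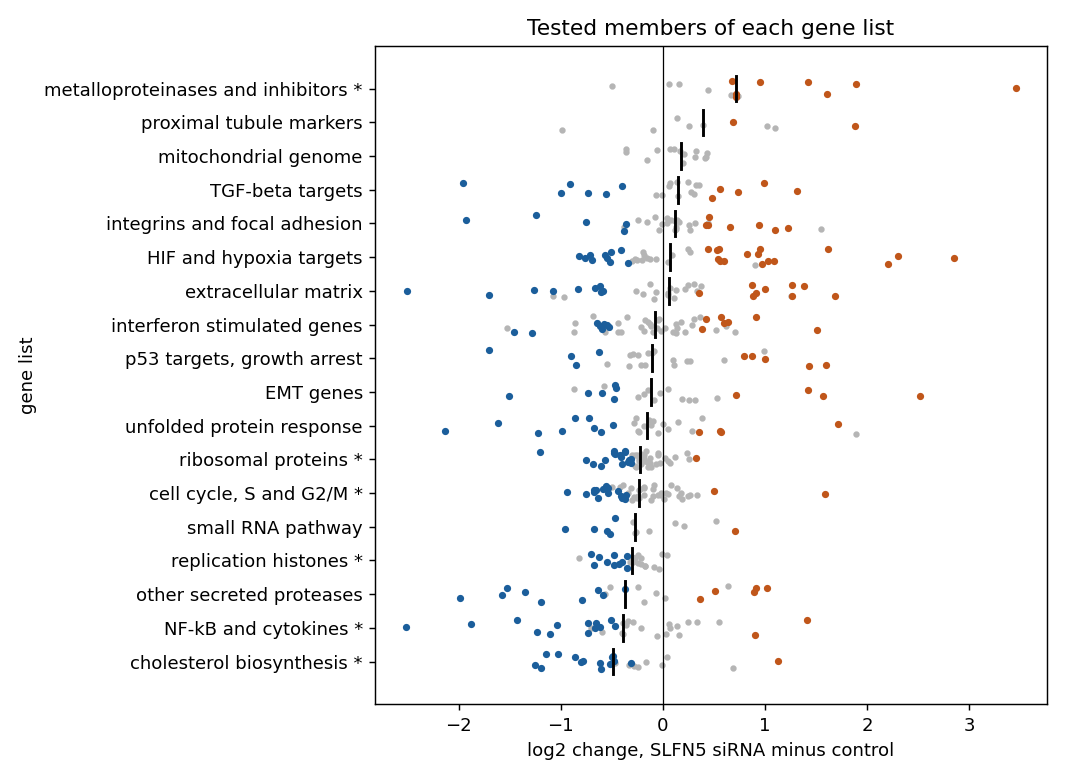
Log2 change (SLFN5 siRNA minus control) of each tested member of 18 of the 19 lists with at least 5 tested members. Orange and blue points passed the threshold as higher and lower, grey points did not, black bars are list medians, and a star marks the 6 lists past camera's adjusted p of 0.05 with the preset correlation; the metalloproteinase list has a median of 0.72 and the cholesterol list one of -0.49.

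Beyond the lists, the genes with the largest increases included ZNF664, a zinc finger gene, which rose 6.54-fold from 310 ± 2.40 to 2033 ± 31.9 equalised counts (SD, n = 2), and TINAG, a kidney basement membrane glycoprotein, which rose 5.77-fold. MYH16, HLA-V, MAP7D2, SIGLEC15, C1orf116 and EVI5L started from mean control values of 10.8 to 45.6 and had log2 changes of 2.56 to 3.41. HLA-V is a pseudogene of the HLA class I family, so its reads may be shared with its relatives. The largest decreases were those of PID1 (ENSG00000153823, log2 change -3.49), the vasoconstrictor peptide gene EDN2 (ENSG00000127129, -3.36), ANKRD46 (-3.34) and the centromere factor MIS18A (-2.84). Endothelin-2 transcripts went from 538 ± 59.1 to 51.3 ± 4.53 equalised counts (SD, n = 2; SE 0.21, limma adjusted p = 4.28e-06). Cyclin A1 (CCNA1), the kinase UHMK1, the YAP target ANKRD1, SGCE and C1orf51 had log2 changes of -2.54, -2.52, -2.46, -2.41 and -2.39. UHMK1 was the most abundant of these, at 8082 ± 508 against 1403 ± 22.0 (SD, n = 2; limma adjusted p = 3.95e-07).

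In all, 4630 of 15640 tested genes passed an adjusted p of 0.05 (limma), 2086 higher and 2544 lower after SLFN5 siRNA, and 807 and 490 of these changed at least 2-fold. The groups did not overlap for 4628 of the 4630 genes, and for 64.6% of all tested genes, against 33.3% by chance. The first principal component held 78.1% of the variance, and the correlation across genes was at least 0.980 within groups and at most 0.967 between them. Without Control 2, the shallowest library, 1346 genes were higher and 1588 lower. With library totals alone in place of composition scaling the median log2 change of all genes moved from -0.03 to 0.09, and the split moved from 45.1% higher to 61.4% higher (2843 higher and 1784 lower).

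**Figure D3:**
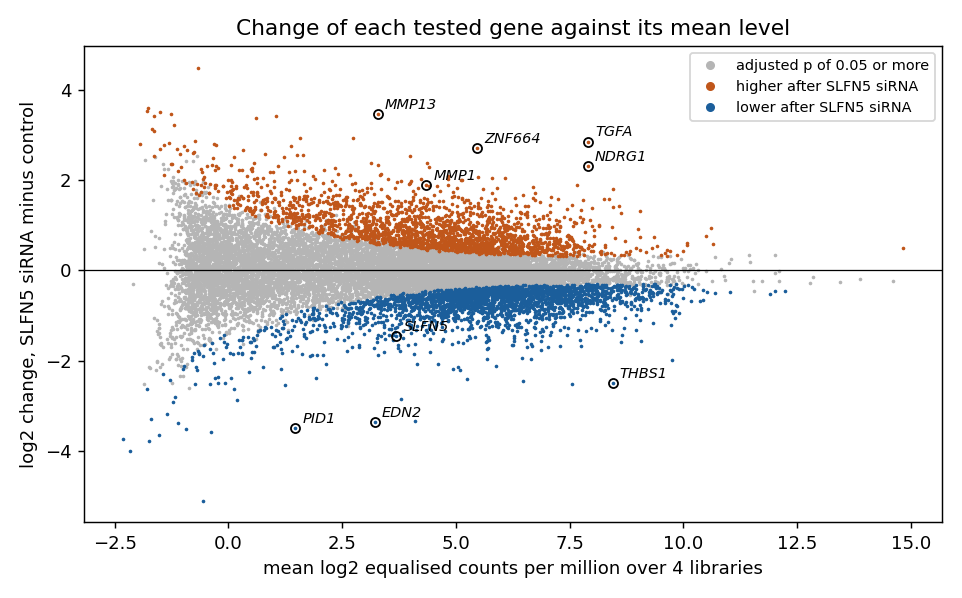
Log2 change (SLFN5 siRNA minus control) of each of the 15640 tested genes against its mean log2 equalised CPM over the 4 libraries, with the 2086 higher genes in orange, the 2544 lower genes in blue and the rest in grey. Circled genes are named in the report; MMP13 has a log2 change of 3.46 and PID1 one of -3.49.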

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

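The removal of a length and GC trend and the run without genes carrying a 3' UTR hexamer were chosen after seeing the data. None of the 4630 calls was made in the other direction under any of 18 alternatives for genes. In some of these the direction could not change. The stricter thresholds, the replicate block and the run without hexamer genes leave each log2 change as it was. Over the named genes, 1638 comparisons with an alternative kept their side of the threshold, 82 were lost and 1 was gained; over the lists these were 317, 23 and 1. Over 17 alternatives the SLFN5 log2 change stayed between -1.70 and -1.20 and past the threshold, and without the hexamer genes SLFN5 itself drops out and has no value. Leaving out each library in turn gave SLFN5 changes from -1.70 to -1.20, 1346 to 1767 higher genes, 1588 to 2341 lower genes and 4 to 7 lists. A lone library left in a group is assumed there to vary like the other group. The 1346 higher and 1588 lower genes came from the fit without Control 2 and include 2800 of the 4630 calls; fewer samples leave less power. A stricter adjusted p under 0.01 left 1145 higher and 1452 lower, and a log2 change of at least 1 left 807 and 490. Without hexamer genes, 8647 genes remained, with 695 higher, 940 lower and 3 lists; the cause was not tested.

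The 6 list calls rest on the preset correlation: 0 lists passed in camera with an estimated correlation (adjusted p of at least 0.760, and 0 at an unadjusted p under 0.05). That run rests on the 2 residual degrees of freedom of the fit, so it has little power. A call lost there cannot tell correlated list members from a test that can hardly pass. In fry, which tests a list against no change and not against other genes, 0 passed (at least 0.0694; 8 at an unadjusted p under 0.05). The replication histone and ribosomal lists passed in all 16 other alternatives (adjusted p up to 0.0168 and 0.0328). The metalloproteinase list failed without hexamer genes (0.161), as did the cholesterol list (0.147) and NF-kB genes (0.342). That run also shortens the lists: 8 of the 14 metalloproteinase and inhibitor genes carry CGGAGA or GGAGAA. A call lost there thus cannot tell an effect of the sites from a list with fewer members. NF-kB genes also failed after trend removal (0.0532), and cell cycle genes after trend removal (0.0732) and with library totals alone (0.0719). Trend removal gave 2222 higher and 2900 lower genes. Lists past no threshold, such as p53, interferon, EMT and matrix genes, changed their camera direction in some alternatives. Of 97 named genes past the threshold besides SLFN5, 81 passed in each alternative that gave them a value, out of 16 without the stricter thresholds; 57 had no value without hexamer genes and 3 none after trend removal.

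With the replicate block, 3008 genes were higher and 3695 lower, all 4630 calls were kept, 6 lists passed and MMP9 passed (adjusted p = 0.0325). The labels do not say what the shared number marks. Deviations of same-numbered libraries correlated across 12315 genes (r = 0.317, rho = 0.352), and genes are not independent replicates. Neither edgeR, the planned count test, nor DESeq2 was run. The replacement fixed for deposited values that are not counts was used, although whole counts could be recovered. Depth was lowest in Control 2, and thinning every library to it gave 1930 higher and 2407 lower genes.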

Other observations

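Chosen only after the result was seen were the gene groups compared first, the tests on base composition of the 3' UTR, those on length and GC content per list and the lists matched by hexamer. Groups of genes sharing the first words of their descriptions or a gene type were compared (98 groups of at least 20 tested genes, camera, preset correlation 0.01). The lowest adjusted p was that of copies of 7SK RNA, with 15 of 117 higher and 0 lower (median log2 change 0.51, adjusted p = 1.69e-07), whose reads cannot be placed with certainty. Genes of the mitochondrial ribosome, which makes the proteins encoded in mitochondria, were lower in 25 of 78 cases and higher in 0 (median log2 change -0.30, adjusted p = 0.000566). Proteasome subunit genes were lower in 25 of 52 cases and higher in 2 (median -0.36, adjusted p = 0.000885). Heterogeneous nuclear ribonucleoproteins, which bind nascent transcripts, were lower in 15 of 34 cases and higher in 2 (median -0.44, adjusted p = 0.00678). Zinc finger genes went the other way, with 145 of 623 higher and 53 lower (median 0.16, adjusted p = 0.00516), as did collagen genes, with 8 of 20 higher and 1 lower (median 0.37, adjusted p = 0.0126). With an estimated correlation none of the 98 groups passed (camera adjusted p of at least 0.773), in a run that rests on 2 residual degrees of freedom and has little power.

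The noncoding RNA 7SK (RN7SK), a regulator of transcription elongation, had a log2 change of 0.51 (SE 0.17, limma adjusted p = 0.0380). The nuclear RNAs MALAT1 and NEAT1 had changes of 0.50 (SE 0.13, adjusted p = 0.0115) and 0.77 (SE 0.18, adjusted p = 0.00678). Small nucleolar RNAs were lower in 23 of 188 cases and higher in 0 (median -0.33, camera adjusted p = 0.00678, and adjusted p = 0.875 with an estimated correlation). RMRP, RN7SL1 and SCARNA2 had log2 changes of -0.23, -0.18 and -0.35 that did not pass (adjusted p = 0.328, 0.559 and 0.136). Of the recovered counts in each library RMRP held 2.19% to 2.65%, RN7SK 2.20% to 3.76% and RN7SL1 1.20% to 1.81%, although these RNAs lack a poly(A) tail and the labels state a selection for it, against 0.0481% to 0.0852% for MALAT1. These genes were chosen after their values were seen, and 7SK has many near-identical copies in the genome.

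The rows of the deposited table stand in 3 consecutive blocks, each sorted by gene identifier. The first holds 956 genes, and all 875 tested there had a positive log2 change. The second holds 570 genes, and all 520 tested there had a negative one. No label says what the blocks are, and 1303 of the 2086 higher and 2079 of the 2544 lower calls lie in the third.

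In an exploratory scan of 7-base words in 3' UTRs, ACAACAT went with the lowest log2 changes (z = -8.77, 1105 of 10546 genes) and GGAGAAA with the highest (z = 8.82), followed by AGGAGAA (8.23), CGGAGAA (6.997), TCGGAGA (6.92), AAGGAGA (6.84) and TGGAGAA (6.43). Each of 2 random sets of 5273 genes gave ACAACAT as the lowest word, and in the set where it was not chosen it lay at least 3.88 units of z below the other 102 words of the same bases, which argues against base composition or UTR length; words sharing 6 bases in a row with it were left out after CAACATA (z = -8.03) was seen in rank 2. The highest words of the 2 sets, GGAGAAA and AGGAGAA, lay 2.37 and 1.71 ahead, so base composition stays open for the words that went with higher values, among them those with GGAGAA (shift 0.12, SE 0.01, 4960 genes), of which 5 of the 6 among the 8 highest do not lie within TCGGAGAA. Seed pairing of the siRNAs, as microRNAs do, is a candidate explanation. The shift went from -0.09 (SE 0.01) for CAACAT to -0.17 (SE 0.02) for ACAACAT and -0.29 (SE 0.03) for ACAACATA. It went from 0.18 (SE 0.02) for CGGAGA to 0.28 (SE 0.04) for TCGGAGA and 0.42 (SE 0.07) for TCGGAGAA. Between libraries of a group it lay between -0.024 and 0.021. Because the 7-base words were picked on these same log2 changes, the growth of the shift with length is not an independent test. ACAACAT, when picked in 1 of the 2 sets, had a shift of -0.17 in the other. The longest SLFN5 transcript holds ACAACAT in 4 places and ACAACATA in 1. Random sequence of its length would hold them at least once in 47.6% and 14.9% of cases. TCGGAGAA would pair with UUCUCCGA, given here from general knowledge and not checked against a source as the start of a strand of a non-targeting siRNA. However, the labels give no siRNA sequence, and a change in microRNAs of the cell with these seeds stays open and was not tested.

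Part of the calls lay in genes with such sites. Genes with ACAACAT made up 16.4% of the 2294 lower calls among the searched genes, and genes with TCGGAGA, 218 of the 10546 searched, 4.57% of the 1730 higher calls. The words were chosen on the same log2 changes, so these shares are not a further test of them. Of the genes with the largest decreases, PID1, UHMK1 and MIS18A carry ACAACAT in the 3' UTR. So do SLFN5 itself (in 3 places), TNC, FERMT1, GBP2, PSAT1, SLC7A11, DNAJB9, STARD4, RPS2 and AGO3, which were lower, and SOD2 and CDH6, which were higher. Of genes named above with TCGGAGA, MMP24, MMP14 and COL14A1 were higher and LTBP2 was lower. EDN2, ANKRD1, SGCE and C1orf51 carry none of the hexamers CAACAT, CGGAGA and GGAGAA.

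The higher calls among metalloproteinase and inhibitor genes (8 of 14) were set against the same sites. The 6 members without CGGAGA or GGAGAA, among them MMP1, had a median log2 change of 0.55 (bootstrap SE 0.28), too few to decide whether seed sites of the control siRNA in the 3' UTRs of the others carry the change. All 6 had a positive log2 change, and 1 was called higher. Of the 8 with a hexamer (median 0.83), 7 were called higher. RECK, also with a hexamer and outside the rule for named genes, had a log2 change of -0.50 that did not pass. Of these 8, MMP15, MMP24, MMP16 and MMP14 carry CGGAGA, whereas MMP13, MMP2, TIMP2 and RECK carry GGAGAA alone. Of the 10546 searched genes, 4960 carry GGAGAA and 927 carry CGGAGA, so a hexamer is common among other genes too. MMP24 and MMP14 carry TCGGAGA, and the explanation by seed sites stays open. Other genes with the same hexamer status and similar expression did not move as far. Over 10000 matched lists of 14 genes, the medians had a mean of -0.004 and a 97.5th percentile of 0.36. The members' 0.72 was reached by 2 lists. Genes were drawn independently of each other and not matched for TCGGAGA. The shifts for GGAGAA (0.12) and CGGAGA (0.18) were already far below 0.72, so this is not an independent test. It shows only that an average shift of these hexamers is too small to be the whole cause. An effect of either siRNA on a regulator of these genes and an effect of SLFN5 cannot be told apart, as the labels name no other siRNA against SLFN5.

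The lower calls among replication histones (10 of 26) and ribosomal proteins (17 of 48) were set against technical causes. After a trend on the length and GC content of the longest annotated transcript was removed, the ribosomal list kept 96.9% of its median change. This argues against that trend as the cause. A bias that follows the length of the transcript expressed in these cells was not tested. Among the 16 of 26 histone genes with a length 106% was kept, and the others could not be tested, so that trend stays open for the list. Without Control 1, the deepest library, the lists kept at least 105% of their medians, which argues against its depth. A difference between the groups in the share of RNA without a poly(A) tail that was taken up may still contribute to the histones and cannot be told apart from the siRNA, as no label gives a library batch, and a change in growth after SLFN5 siRNA was not tested.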
